A study of Mus musculus with 24 samples.

How the data were processed

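RNA was measured by sequencing in 24 libraries from whole mouse hearts. Per the labels, the hearts were homogenized in TRIzol, total RNA was precipitated from the aqueous phase, and libraries were made with a strand-specific kit (NEBNext Ultra II Directional). The labels give 4 genotypes with 6 libraries each, and 2 batches that each hold 3 libraries of every genotype. They do not say that each library came from a separate animal, so p-values measure the spread between these libraries.

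The authors deposited 1 table of read counts per Ensembl gene and 5 tables of their own comparisons. The deposited counts are whole numbers, not normalized. Per the submitters' processing notes, the tools used were bcl2fastq 2.17, FastQC, Trim Galore, STAR and RSEM, and the genome build was mm10 (GRCm38). The role of each tool, the annotation used for counting and the strand setting are not given in the sources used here, nor whether RSEM estimates were rounded to give the whole numbers. Such estimates divide reads that match several genes, so the level of a gene with a near-identical copy is less certain than its count error shows. Per the file headers, the authors' comparison tables hold a log2 fold change, a mean log2 expression, a test statistic (a score), a p-value and an adjusted p-value per gene. In those deposited tables the statistic is 0 for every gene with a log2 fold change below 0.263 in size, which is a fold of 1.2, so they test against a minimum fold.

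The count table has 56384 rows, of which 3660 are named by a transcript and by no gene, and the others are gene rows. The transcript-named rows held 0.873 to 4.28% of the counts of a library and were left out of library sizes and tests. Of these rows 498 had any count and 3653 matched a gene of the GENCODE M21 annotation. Of the genes tested, 43 had over 10% of their counts in such rows, and 1 of those was called in any comparison, Adora1 in FKl/l MHC+ against FKl/l (adjusted p = 0.0454, lost in 17 of the 24 fits that left out 1 library, up to 0.127), named after its values were seen. The gene rows summed to between 27799403 and 40412640 counts per library. Mitochondrially encoded genes took 25.7 to 36.5% of these counts. No 2 libraries of a genotype were alike within counting noise, since the chi-square per degree of freedom between libraries of a genotype lay between 8.37 and 99, where counting noise alone gives about 1.

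Gene names were taken from the count table. Positions are those of GENCODE M21 on GRCm38, in which 51939 of the gene rows had an entry. Levels are counts-per-million values (CPM) computed here on library sizes scaled by edgeR's trimmed mean of M values (TMM). The main test was edgeR's quasi-likelihood F-test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) on the deposited counts, after filterByExpr by genotype, which left 16018 genes with at least 99.89% of each library's counts. The 24 libraries entered 1 fit with a term for each genotype and a term for batch, so that all genotypes shared 1 estimate of the spread. Dispersions and the quasi-likelihood fit were robust. A gene was called where its 2-sided p, adjusted by Benjamini-Hochberg over all genes tested in that comparison, was under 0.05, with no minimum fold. Adjusted p-values in the text come from this test unless another is named. The error beside a log2 fold change is its standard error (SE).

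There were 5 comparisons, which share libraries. Each deletion genotype was set against the floxed genotype without Cre, the MHC deletion also against the MHC Cre driver without the floxed allele, the driver against the floxed genotype, and the deletions against each other. The interaction of genotype with batch was tested in a fit that added these terms. For the 2 deletions set against the same FKl/l libraries, the overlap of calls was compared with 20 simulated sets of unchanged libraries and with 18 splits of the control libraries into 2 sets.

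Before the data were examined, 40 gene lists were written for pathways of the heart, FKBP proteins, and markers of heart and other cell types, of sex, of handling and of time of day. They hold 865 entries, of which 853 were found in the count table, and each list had at least 5 members tested. Each list was tested with camera at a preset correlation of 0.01 between genes, with adjustment over the 40 lists of a comparison. The test was repeated with an estimated correlation and with fry, by its directional test unless its mixed test is named. Counts of list members called over all genes are given beside counts adjusted over the list alone.

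The rule for naming genes was also fixed before the data were examined. It takes Fkbp1a and Fkbp1b. It takes, in each comparison, up to 10 called genes with the highest and 10 with the lowest log2 fold change among those with a mean of at least 5 CPM in a group compared, the same sign in both batches and a symbol that is not a predicted name or sex-linked. From each list described it takes up to 4 called members with the smallest adjusted p, or, where none is called, the 2 members with the highest mean CPM. The text gives fewer than the rule allows, and says where a gene was named outside it.

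The alternatives fixed before the data were examined were RLE size factors, DESeq2 1.42.0, limma voom with quality weights, no filter on low counts and a stricter one, no batch term, the replicate number as a block, only the 2 genotypes compared, each batch alone, a minimum fold of 2, libraries without mitochondrially encoded genes, a term for Y-linked transcripts, and leaving out each library in turn. Those added after the data were seen were a test against a fold of 1.2, transcript-named rows added to their genes, a term for airway transcripts, leaving out 3 libraries, leaving out genes near Fkbp1a, and the FKBP list without Fkbp1a. Other splits of the same libraries were refitted 100 times for each count.

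The tests were tried on simulated counts drawn from the means, dispersions and library sizes of FKl/l MHC+ against FKl/l, over 16018 genes. Among 50 genes changed by each fold, edgeR recovered 34% at 1.3-fold, 58% at 1.5-fold, 96% at 2-fold and 98% at 4-fold, and 3.85% of its calls were false. DESeq2 recovered 38%, 62%, 96% and 98%, with 9.88% of its calls false. In a set with no change edgeR called 0 genes with 4.58% of genes at an unadjusted p under 0.05, and camera called 0 of 40 lists. Genes were drawn independently of each other, so these sets do not show how camera performs where genes vary together. In other splits of the real libraries, given below, camera at the preset correlation called up to 19 lists. A list of 18 genes shifted by 1.25-fold ranked first of the 40, with an adjusted p of 3.72e-17 at the preset correlation and 4.21e-07 with an estimated one. At this depth and number of libraries a change of 1.3-fold is therefore missed in most genes.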

Results

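RNA was sequenced from whole hearts of mice in which the gene Fkbp1a carried floxed alleles and Cre recombinase was expressed from a muscle promoter. Fkbp1a encodes FKBP12, a small immunophilin that binds the drugs FK506 and rapamycin and associates with ryanodine receptors. The 4 genotypes were floxed mice without Cre (FKl/l), mice with αMHC-driven Cre and no floxed allele (MHC CRE Only), floxed mice with MCK-driven Cre (FKl/l MCK+) and floxed mice with αMHC-driven Cre (FKl/l MHC+). Per the study's design, the αMHC promoter is active from embryonic day 9 and the MCK promoter from day 13. Each genotype had 6 libraries, 3 in each of 2 batches, and a library is named by its genotype, batch and number. Library sizes ranged from 27799403 counts in FKl/l MCK+ 2-3 to 40412640 in FKl/l MCK+ 1-2. Whole hearts contain endothelial cells, fibroblasts and other cells beside cardiomyocytes, and a transcript level is that of the mixture.

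Fkbp1a (ENSMUSG00000032966), on the plus strand of chromosome 2 from 151542483 to 151561692 in GRCm38, was lower in both deletion genotypes. Its level was 130 ± 10.1 CPM in FKl/l (SD, n = 6), with libraries between 121 and 147. In FKl/l MCK+ it was 65.1 ± 10.7 CPM (SD, n = 6), with libraries between 51.1 and 81.1. This is 49.8% of the FKl/l level (log2 fold change -1.0, SE 0.125, adjusted p = 0.00032 by edgeR's quasi-likelihood test). In FKl/l MHC+ it was 59.1 ± 12.6 CPM (SD, n = 6), with libraries between 43.5 and 75.7. This is 45.1% of FKl/l (log2 fold change -1.15, SE 0.125, adjusted p = 5.47e-06). In MHC CRE Only it was 122 ± 20.6 CPM (SD, n = 6), and 5 of these libraries lay between 122 and 138. The library labelled MHC CRE Only 1-3 had 81.8 CPM, below every FKl/l library and near the highest deletion library, so its Fkbp1a level goes against its label. Without it the other 5 libraries averaged 130 ± 6.33 CPM (SD, n = 5). The deletion genotypes did not differ from each other by the test (log2 fold change -0.14, SE 0.124, adjusted p = 0.638). Nor did MHC CRE Only differ from FKl/l (log2 fold change -0.09, SE 0.123, adjusted p = 0.813). Within batches 1 and 2 the log2 fold change against FKl/l was -0.98 and -1.05 for FKl/l MCK+ and -1.02 and -1.26 for FKl/l MHC+. The counts cover the whole gene and the labels do not say which part Cre removes. The paralog Fkbp1b, which encodes FKBP12.6, had a mean of at most 0.51 CPM in any genotype and was called in no comparison.

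**Figure D1:**
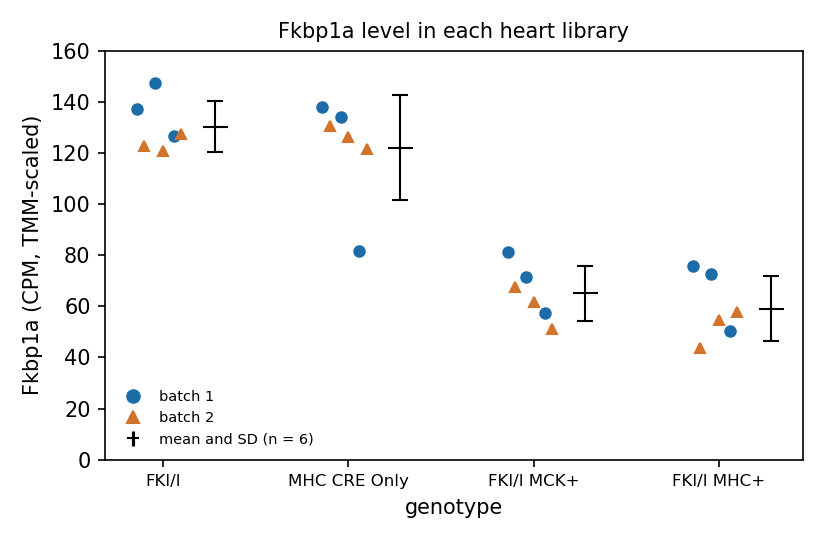
Points are the Fkbp1a level of each library in TMM-scaled CPM by genotype (circles batch 1, triangles batch 2), and bars give the mean and SD of 6 libraries. Libraries of the deletion genotypes sit between 43.5 and 81.1 CPM and those of FKl/l between 121 and 147, with the library labelled MHC CRE Only 1-3 at 81.8.

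More genes differed between batches than between any genotypes compared. Of 16018 genes tested, 6158 differed between batches, 3560 of them higher in batch 2. Mitochondrially encoded transcripts took 35.1 ± 1.17% of counts in batch 1 and 26.3 ± 0.594% in batch 2 of MHC CRE Only (SD, n = 3 each), and 35 ± 1.15% and 28.5 ± 0.31% in FKl/l MHC+. In FKl/l these shares were 32 ± 4.23% and 29.1 ± 0.204%, and in FKl/l MCK+ 34 ± 4.27% and 29 ± 1.39%. Markers of lung and airway epithelium were highest in MHC CRE Only 2-3 and FKl/l 1-1, with mean log2 CPM of the list 4.48 and 3.06 above their batch mean, where the next library had 1.69. The airway secretoglobin Scgb1a1, named after its values were seen, averaged 67.6 CPM in MHC CRE Only and 18.6 CPM in FKl/l, against 2.28 CPM in FKl/l MCK+ and 5 CPM in FKl/l MHC+. All comparisons were fitted with a batch term.

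The comparison of FKl/l MCK+ with FKl/l measures the deletion of Fkbp1a by the later driver together with the MCK-Cre transgene, since no libraries carried that transgene without the floxed allele. Few genes changed, 8 of 16018, and apart from Fkbp1a all 7 were higher. Kcne1, an auxiliary subunit of a cardiac potassium channel, rose 3.4-fold, from 2.27 ± 0.728 to 7.66 ± 3.32 CPM (SD, n = 6 each; log2 fold change 1.77, SE 0.255, adjusted p = 0.00241). Cpne5, which encodes a copine, rose 1.96-fold (log2 fold change 0.97, SE 0.13, adjusted p = 0.00032). Masp1, a serine protease of the lectin pathway of complement, rose 1.62-fold (log2 fold change 0.69, SE 0.106, adjusted p = 0.00228). Fbln1, a matrix glycoprotein expressed by fibroblasts, rose from 121 to 178 CPM (log2 fold change 0.55, SE 0.0939, adjusted p = 0.00859). Hamp, which encodes the iron-regulating hormone hepcidin, rose 1.59-fold, Fam78a 1.36-fold, and Cntn2, a cell adhesion protein of the conduction system, 1.33-fold, with adjusted p-values of 0.012, 0.0336 and 0.0336. The Hamp call was lost without FKl/l MCK+ 2-3, FKl/l 2-2 or FKl/l 2-3 (adjusted p up to 0.059). The Fam78a call was lost without any library of the 2 genotypes except FKl/l 1-2 and FKl/l MCK+ 1-1 (up to 0.124), and the Cntn2 call without any except FKl/l 1-1 and FKl/l MCK+ 2-1 (up to 0.199). All 8 genes kept their sign in both batches. Such agreement is largely built in, here and in the comparisons below, since genes were called on both batches together. Batch 1 alone gave 1 call, also among the 8, and batch 2 alone gave 8, of which 3 were among them.

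Between FKl/l MCK+ and FKl/l, 9 of the 40 gene lists were called at the preset correlation and 0 with an estimated correlation or by fry. The count of 9 was 14 without FKl/l MCK+ 2-1 and 19 without FKl/l 1-3. At an unadjusted p under 0.05, 839 genes passed. The 23 immediate early genes were lower as a group (adjusted p = 5.91e-07, or adjusted p = 0.552 with an estimated correlation) with no member called. Enzymes of branched-chain amino acid breakdown were lower (21 genes, adjusted p = 2.38e-06, or adjusted p = 0.46 with an estimated correlation), with 0 called over all genes and 1 lower adjusted over the list alone. Fibroblast markers were higher (18 genes, adjusted p = 2.38e-06, or adjusted p = 0.349 with an estimated correlation), with 1 called, Fbln1, and 2 adjusted over the list alone. Endothelial markers were higher (18 genes, adjusted p = 0.000255, or adjusted p = 0.552 with an estimated correlation). Adipocyte markers were lower (14 genes, adjusted p = 1.21e-05, or adjusted p = 0.552 with an estimated correlation). No member of either was called. Extracellular matrix genes (36, adjusted p = 1.21e-05) and erythroid markers (9, adjusted p = 6.53e-05) were higher, each with adjusted p = 0.552 with an estimated correlation. Both calls were lost without FKl/l MCK+ 1-2, at adjusted p = 0.227 and 0.0747, and the erythroid markers had the opposite sign in batch 2 (adjusted p = 0.774). Lower sets with adjusted p near the threshold were the unfolded protein response (21 genes, adjusted p = 0.0221, or adjusted p = 0.552 with an estimated correlation) and the tricarboxylic acid cycle (23 genes, adjusted p = 0.0358, or adjusted p = 0.659 with an estimated correlation). These 2 calls were lost without FKl/l MCK+ 1-2, FKl/l MCK+ 2-3, FKl/l 2-2 or FKl/l 2-3, and that of the cycle also without FKl/l 1-2 or FKl/l 2-1 (adjusted p up to 0.143 and 0.227). The count of 8 genes became 5 without FKl/l MCK+ 2-3, FKl/l 2-2 or FKl/l 2-3, 5 without a batch term, 4 with a term for Y-linked transcripts and 3 when tested against a fold of 1.2. It was 17 by DESeq2 and 13 by limma voom.

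The comparison of FKl/l MHC+ with FKl/l measures the deletion of Fkbp1a by the earlier driver together with the MHC-Cre transgene, which FKl/l does not carry. It gave 274 genes, 170 higher and 104 lower, of which 38 changed at least 2-fold. Some transcripts of fast skeletal muscle were higher. Mylpf, a fast myosin light chain, rose 4.96-fold from 0.37 ± 0.132 to 1.85 ± 0.767 CPM (SD, n = 6 each; log2 fold change 2.31, SE 0.276, adjusted p = 7.33e-06). Atp2a1, the calcium pump SERCA1 of fast muscle, rose 2.87-fold to 12 ± 3.39 CPM (adjusted p = 0.000266). Mybpc2, the fast myosin-binding protein C, rose 2.15-fold to 50.1 ± 15.7 CPM (adjusted p = 0.0035). Genes of the fetal and stress program of cardiomyocytes were also higher. Ankrd1, a stretch-responsive nuclear and sarcomeric protein, was at 2433 ± 888 CPM against 1150 ± 710 CPM (SD, n = 6 each; log2 fold change 1.2, SE 0.145, adjusted p = 2.37e-05).

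Of the 10 skeletal muscle markers tested against FKl/l, 4 were called higher, 0 lower and 6 were not called, with 6 higher and 1 lower adjusted over the list alone (adjusted p = 3.05e-10, or adjusted p = 0.00543 with an estimated correlation). The other called member was the fast troponin Tnni2 (log2 fold change 1.05, SE 0.219, adjusted p = 0.00881). The fetal and stress program had 6 of 24 members called higher and 0 lower, with 6 higher and 1 lower adjusted over the list alone (adjusted p = 1.31e-07, or adjusted p = 0.0259 with an estimated correlation). The latter call was lost without FKl/l 2-2 or FKl/l 2-3, with an adjusted p of up to 0.0702. Its called members included the deubiquitinase Uchl1 (log2 fold change 0.59, SE 0.0912, adjusted p = 0.000372) and the metallothionein Mt2, which rose 3.2-fold (log2 fold change 1.68, SE 0.308, adjusted p = 0.00569). Enzymes of branched-chain amino acid breakdown were lower, with 5 of 21 called lower and 7 adjusted over the list alone (adjusted p = 8.84e-10, or adjusted p = 0.0737 with an estimated correlation). Among them were Bckdha and Bckdhb, the E1 subunits of the branched-chain ketoacid dehydrogenase, at log2 fold changes of -0.48 (SE 0.0869, adjusted p = 0.00241) and -0.40 (SE 0.0785, adjusted p = 0.00497). Mccc2 of leucine breakdown was at -0.38 (SE 0.0665, adjusted p = 0.00207). Endothelial markers were lower as a group (18 genes, adjusted p = 3.85e-07, or adjusted p = 0.125 with an estimated correlation). The vascular receptor Robo4 was the called member (log2 fold change -0.32, SE 0.067, adjusted p = 0.0076), and 10 were lower adjusted over the list alone. Targets of p53 were higher (25 genes, adjusted p = 0.000554, or adjusted p = 0.141 with an estimated correlation), with 3 called higher and 1 lower over all genes and 4 and 1 adjusted over the list alone. Cdkn1a, the cell cycle inhibitor p21, rose from 36.3 ± 6.62 to 87.9 ± 23.3 CPM (SD, n = 6 each; log2 fold change 1.29, SE 0.179, adjusted p = 0.000382).

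Further lists against FKl/l were called at the preset correlation and not with an estimated correlation, the Notch pathway also by fry (adjusted p = 0.027). Higher lists were the heat shock response (18 genes, adjusted p = 0.000556, or adjusted p = 0.602 with an estimated correlation) and macrophage and monocyte markers (21 genes, adjusted p = 0.00422, or adjusted p = 0.57 with an estimated correlation). So were sarcomere and Z-disc genes (25 genes, adjusted p = 0.00558, or adjusted p = 0.602 with an estimated correlation). Called members were Hspb1 in the first (log2 fold change 0.47, SE 0.103, adjusted p = 0.0115), 0 in the second and 1 in the third. Interferon response genes were lower (30 genes, adjusted p = 0.00422, or adjusted p = 0.654 with an estimated correlation), a call lost without FKl/l 2-2 or FKl/l MHC+ 2-2 (adjusted p up to 0.885). The tricarboxylic acid cycle was lower (23 genes, adjusted p = 0.0203, or adjusted p = 0.654 with an estimated correlation), a call lost without FKl/l 1-2, FKl/l 2-1 or FKl/l 2-2 (adjusted p up to 0.0689). Extracellular matrix and integrated stress response genes were higher, and fatty acid oxidation and Notch pathway genes lower, each at adjusted p = 0.0436. Lymphocyte markers were lower at adjusted p = 0.0446. With an estimated correlation these had adjusted p = 0.654, adjusted p = 0.318, adjusted p = 0.654, adjusted p = 0.259 and adjusted p = 0.654 in that order. They were lost in 5, 6, 10, 6 and 8 of the 24 fits that left out 1 library, with adjusted p-values of up to 0.14, 0.149, 0.112, 0.0633 and 0.221. All of these include the fit without FKl/l 2-2, or FKl/l 2-3 for the Notch pathway. The matrix members Thbs4 (log2 fold change 0.83, SE 0.142, adjusted p = 0.00157) and Timp1 (log2 fold change 1.24, SE 0.23, adjusted p = 0.00322) were called higher.

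Among other single genes, Kcne1 rose 3.42-fold to 7.83 ± 2.61 CPM (log2 fold change 1.77, SE 0.256, adjusted p = 0.000426) and Masp1 2.36-fold (log2 fold change 1.24, SE 0.106, adjusted p = 4.28e-08). Epn3, an epsin of endocytosis, rose 2.33-fold to 62.3 ± 7.97 CPM (adjusted p = 0.00361). Gdf15, a stress-induced cytokine, rose 4.01-fold (log2 fold change 2.00, SE 0.482, adjusted p = 0.035). That call was lost without FKl/l 1-2, FKl/l 1-3, FKl/l 2-1, FKl/l 2-2, FKl/l MHC+ 1-2 or FKl/l MHC+ 2-3 (adjusted p up to 0.0931). Dmd, which encodes dystrophin, was at 20.3 ± 2.63 CPM against 36 ± 4.25 CPM (SD, n = 6 each; log2 fold change -0.82, SE 0.0755, adjusted p = 1.08e-07). The ephrin ligand Efnb3 (log2 fold change -0.88, SE 0.103, adjusted p = 7.34e-06) and the cytokine Il15 (log2 fold change -0.73, SE 0.1, adjusted p = 6.49e-05) were also lower. All 274 genes had the same sign in both batches, which is largely built in since both entered the calls. There were 209 calls in batch 1 alone (88 of them among the 274) and 161 in batch 2 alone (91). The count of 274 lay between 155 and 163 without FKl/l 1-2, FKl/l MHC+ 1-2, FKl/l MHC+ 1-3 or FKl/l MHC+ 2-3. It was 415 without FKl/l MCK+ 1-2 and 420 without the library labelled MHC CRE Only 1-3. It was 558 by DESeq2, 881 by limma voom, 120 without a batch term, 42 tested against a fold of 1.2 and 506 without the library labelled MHC CRE Only 1-3, MHC CRE Only 2-3 and FKl/l 1-1.

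The deletions shared 7 genes called with the same sign against FKl/l, which were Fkbp1a, Kcne1, Masp1, Cpne5, Hamp, Fam78a and Cntn2. The call of Cpne5 in FKl/l MHC+ was lost without FKl/l 1-1 or 1-3 or FKl/l MHC+ 1-2, 1-3 or 2-1 (adjusted p up to 0.0702). Those of Hamp, Fam78a and Cntn2 in FKl/l MCK+ were lost without some libraries (adjusted p up to 0.059, 0.124 and 0.199). Of the genes called in FKl/l MCK+ only Fbln1 was not called in FKl/l MHC+. Independent lists of these sizes would share 0.0808 genes, and 20 simulated pairs of unchanged groups against the same controls shared a median and a maximum of 0. Unchanged groups give almost no calls, so that 0 was set in advance and does not weigh the 7 shared genes. Of the 7, Fkbp1a is the gene deleted in both genotypes by design. With the FKl/l libraries split so that each deletion had its own controls, 18 splits shared a median of 1 gene (range 1 to 3). Across genes, which are not independent replicates, the log2 fold changes of the 2 comparisons correlated at 0.476, against a median of 0.506 and a maximum of 0.561 in the simulated pairs. Their covariance was 0.0379 against 0.0329 simulated, a difference of 0.00492, and the median over the split controls was -0.0129.

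The comparison of FKl/l MHC+ with MHC CRE Only sets the deletion against hearts with the same Cre driver, in groups that also differ in the floxed allele. It gave 299 genes, 174 higher and 125 lower, 36 of them at least 2-fold. The fetal and stress program was again higher, with Ankrd1 at 2433 ± 888 against 996 ± 436 CPM (SD, n = 6 each; log2 fold change 1.35, SE 0.145, adjusted p = 1.53e-05). Genes of the unfolded protein response were lower, among them Manf, an endoplasmic reticulum stress protein, at 53.9 ± 8.54 against 80.7 ± 11.8 CPM (SD, n = 6 each; log2 fold change -0.57, SE 0.0978, adjusted p = 0.00187). Fkbp1a was at 48% of the MHC CRE Only level (log2 fold change -1.06, SE 0.125, adjusted p = 4.46e-05; -0.80 in batch 1 and -1.29 in batch 2), where the controls include the library labelled MHC CRE Only 1-3.

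Of 21 unfolded protein response genes, 7 were called lower and 0 higher, and 10 were lower adjusted over the list alone (adjusted p = 4.99e-10, or adjusted p = 0.0272 with an estimated correlation). The latter call was lost without MHC CRE Only 1-1, MHC CRE Only 1-2 or FKl/l MHC+ 2-1 (adjusted p up to 0.0647). Called members included the chaperone Hyou1 (log2 fold change -0.34, SE 0.0615, adjusted p = 0.00291) and the ubiquitin ligase Syvn1 (log2 fold change -0.36, SE 0.0676, adjusted p = 0.00394). The same list was higher in MHC CRE Only than in FKl/l (adjusted p = 2.09e-06, or adjusted p = 0.21 with an estimated correlation), and it was not called between FKl/l MHC+ and FKl/l. Of the 24 fetal and stress genes, 3 were called higher and 0 lower, with 8 higher adjusted over the list alone (adjusted p = 9.48e-08, or adjusted p = 0.0272 with an estimated correlation). Uchl1 was among them (log2 fold change 0.50, SE 0.091, adjusted p = 0.00305). Of 14 FKBP family genes, Fkbp1a and Fkbp10, a collagen-folding enzyme of the endoplasmic reticulum, were called lower and 12 were not called, as adjusted over the list alone (adjusted p = 0.00411, or adjusted p = 0.0272 with an estimated correlation). Fkbp10 had a log2 fold change of -0.46 (SE 0.0818, adjusted p = 0.00232). The list contains the deleted gene, and without Fkbp1a it was not called (adjusted p = 0.122, or adjusted p = 0.328 with an estimated correlation), a test chosen after the result was seen. With Fkbp1a, the estimated-correlation call was lost without MHC CRE Only 1-1, MHC CRE Only 1-2, FKl/l MHC+ 2-1 or FKl/l MHC+ 2-2 (adjusted p up to 0.0998). Sex-linked transcripts were higher, with 2 of 6 called and 3 adjusted over the list alone (adjusted p = 0.000179, or adjusted p = 0.0272 with an estimated correlation, and 0.0558 without FKl/l MHC+ 2-1). The Y-linked Ddx3y was at 42 ± 7.63 against 30 ± 3.64 CPM (SD, n = 6 each; log2 fold change 0.49, SE 0.0966, adjusted p = 0.00701). The other called member was Xist, at 1.18 ± 0.623 against 0.364 ± 0.207 CPM (adjusted p = 0.0444), a call lost in 16 of the 24 fits that left out 1 library (adjusted p up to 0.114). A Y-linked transcript and the X-linked Xist were thus both higher, so the list call does not show a difference in sex.

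Heat shock genes were higher against MHC CRE Only (18 genes, adjusted p = 2.89e-06, or adjusted p = 0.328 with an estimated correlation). The chaperone Hsp90aa1 was called (log2 fold change 0.92, SE 0.18, adjusted p = 0.0102), and 8 were higher adjusted over the list alone. Immediate early genes were higher (23 genes, adjusted p = 0.000413, or adjusted p = 0.558 with an estimated correlation), with 0 called and 4 higher adjusted over the list alone. Skeletal muscle markers were higher (10 genes, adjusted p = 0.00108, or adjusted p = 0.126 with an estimated correlation), with 2 called and 3 adjusted over the list alone. Mylpf was at 0.838 ± 0.141 CPM in MHC CRE Only (log2 fold change 1.13, SE 0.258, adjusted p = 0.0199, and up to 0.0873 without FKl/l MHC+ 1-2 or FKl/l MHC+ 2-3). Mybpc2 was at 28.4 ± 7.57 CPM (log2 fold change 0.83, SE 0.19, adjusted p = 0.0277). Its call was lost without FKl/l MHC+ 1-2, 1-3 or 2-3 or without MHC CRE Only 1-2, 2-1, 2-2 or 2-3 (adjusted p up to 0.0723). Macrophage and monocyte markers were higher (21 genes, adjusted p = 0.00298, or adjusted p = 0.507 with an estimated correlation). Endothelial markers were lower (18 genes, adjusted p = 0.000884, or adjusted p = 0.328 with an estimated correlation). Of these Robo4 was called (log2 fold change -0.33, SE 0.067, adjusted p = 0.00791), and 6 were lower adjusted over the list alone. Also lower were branched-chain amino acid breakdown (21 genes, adjusted p = 0.0015, or adjusted p = 0.413 with an estimated correlation) and the Notch pathway (16 genes, adjusted p = 0.0155, or adjusted p = 0.164 with an estimated correlation). Smooth muscle and pericyte markers were lower (15 genes, adjusted p = 0.0102, or adjusted p = 0.209 with an estimated correlation, and adjusted p = 0.0614 without MHC CRE Only 2-3), with the pericyte receptor Pdgfrb called (log2 fold change -0.33, SE 0.0576, adjusted p = 0.00183). Another 6 lists had an adjusted p between 0.0173 and 0.0313 at the preset correlation, and an adjusted p between 0.558 and 0.715 with an estimated correlation. These were erythroid markers, sarcomere genes, cell cycle genes and mitochondrially encoded genes, which were higher, and the tricarboxylic acid cycle and fibroblast markers, which were lower. The last 2 had the opposite sign in 1 batch (adjusted p = 0.196 and 0.933). Each of the 6 was lost in 2 to 6 of the 24 fits that left out 1 library, among them those without 1 or more of MHC CRE Only 1-1, 2-1 and 2-2 (adjusted p up to 0.283). The sarcomere genes changed most without MHC CRE Only 2-3 (0.232).

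Single genes higher against MHC CRE Only included Kcne1 (log2 fold change 1.26, SE 0.249, adjusted p = 0.00989) and Masp1 (log2 fold change 1.09, SE 0.106, adjusted p = 6.74e-07). Others were Thbs4 (log2 fold change 1.03, SE 0.143, adjusted p = 0.000225) and Cdkn1a (log2 fold change 0.89, SE 0.177, adjusted p = 0.0122). Efnb3 was lower (log2 fold change -0.74, SE 0.103, adjusted p = 0.000227). The brain-type glycogen phosphorylase Pygb was at 547 ± 62.5 against 882 ± 53.4 CPM (SD, n = 6 each; log2 fold change -0.70, SE 0.0876, adjusted p = 4.46e-05). Pygb lies 0.711 Mb from Fkbp1a and was at 554 CPM in FKl/l, from which FKl/l MHC+ did not differ (log2 fold change 0.002, adjusted p = 0.996). Of 107 genes tested within 5 Mb of Fkbp1a, 5.61% were called here, against 1.84% elsewhere (Fisher's exact test, two-sided, p = 0.0151). The photoreceptor lipid transporter Abca4 was at 2.49 ± 0.63 against 5.17 ± 0.876 CPM (log2 fold change -1.06, SE 0.164, adjusted p = 0.000569). All 299 genes had the same sign in both batches, with 79 genes called in batch 1 alone (41 of them among the 299) and 924 in batch 2 alone (150). Of the 299, 6 also differed in effect between batches by an interaction test. The count of 299 was between 135 and 143 without FKl/l MHC+ 1-2, 1-3 or 2-3, 164 and 190 without MHC CRE Only 2-1 and 2-2, and 496 without FKl/l MHC+ 2-1. It was 51 with a term for Y-linked transcripts, 42 without a batch term, 17 tested against a fold of 1.2, 516 with a term for airway transcripts, 571 by DESeq2 and 708 by limma voom. The Y-linked term includes Ddx3y, which was called between these genotypes, so it can take up differences between them.

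Against both FKl/l and MHC CRE Only, 95 genes were called in FKl/l MHC+, 62 higher and 33 lower, and none with opposite signs. This count was between 52 and 62 without FKl/l MHC+ 1-2, 1-3 or 2-3 or MHC CRE Only 2-1, 165 without FKl/l MHC+ 2-1 and 144 without the library labelled MHC CRE Only 1-3. It was 31 with a term for Y-linked transcripts, 29 without a batch term, 26 in batch 1 alone, 13 tested against a fold of 1.2, 185 by DESeq2 and 292 by limma voom. They included Ankrd1, Kcne1, Masp1, Cdkn1a, Thbs4 and Uchl1, which were higher, and Dmd, Efnb3 and Robo4, which were lower. Dmd had a log2 fold change of -0.49 against MHC CRE Only (adjusted p = 0.000511).

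**Figure D2:**
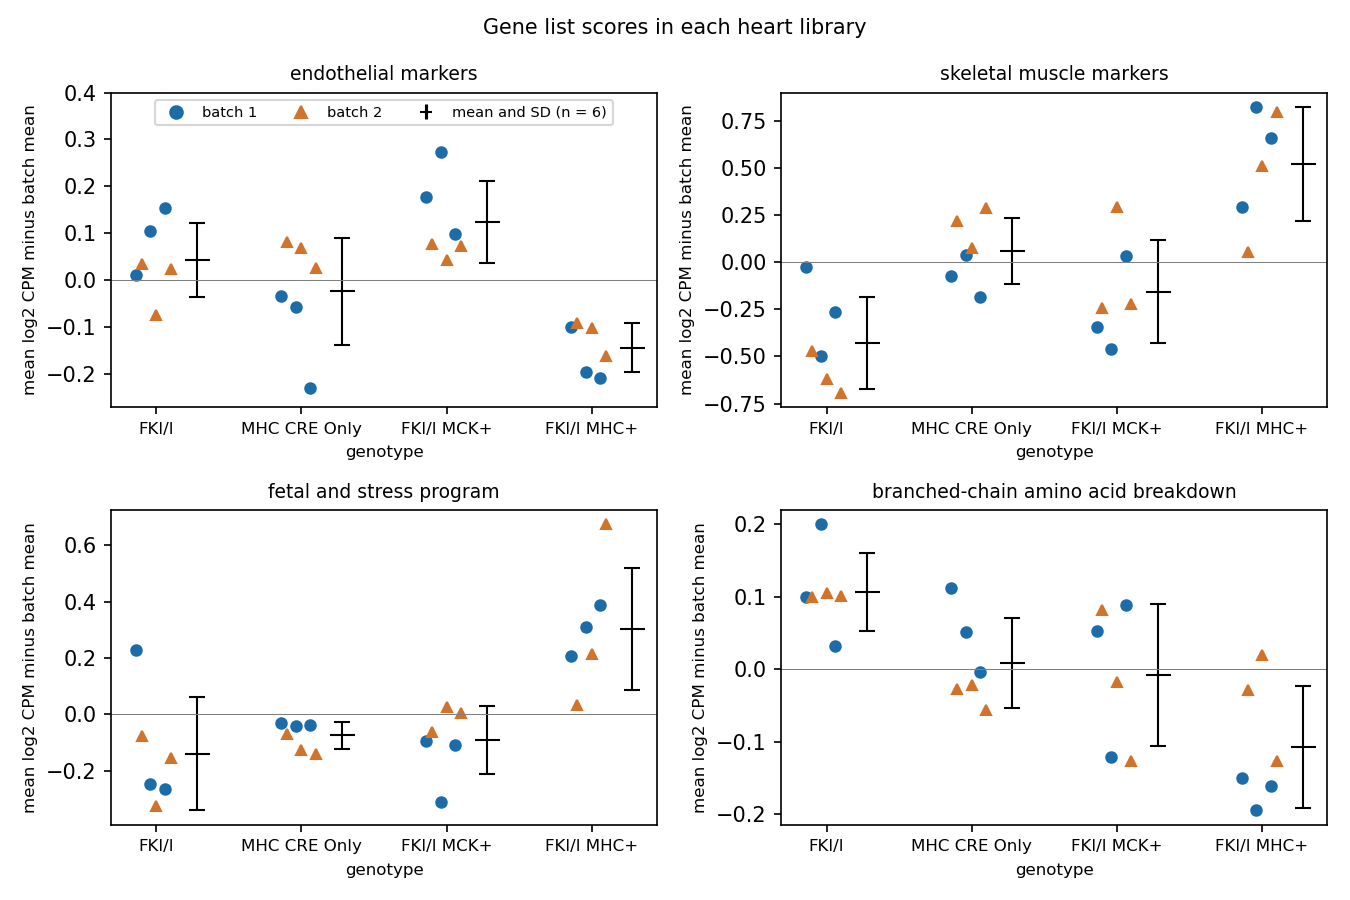
Each point is the mean log2 CPM of a gene list in 1 library minus the mean of its batch, by genotype (circles batch 1, triangles batch 2), and bars give the mean and SD of 6 libraries. Endothelial scores of FKl/l MHC+ lie between -0.21 and -0.09 and those of FKl/l MCK+ between 0.04 and 0.27, with the library labelled MHC CRE Only 1-3 at -0.23. Skeletal muscle scores of FKl/l MHC+ lie between 0.05 and 0.82 and those of FKl/l between -0.69 and -0.03.

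The comparison of MHC CRE Only with FKl/l measures the driver without deletion, in groups that also differ in the floxed allele and with the library labelled MHC CRE Only 1-3 among them. It gave 7 genes, 5 higher and 2 lower, 1 of them at least 2-fold. Of these, 6 lie on chromosome 2 between 150786735 and 153404007 in GRCm38, within 1.78 Mb of Fkbp1a. Pygb, the brain-type glycogen phosphorylase, was at 882 ± 53.4 CPM in MHC CRE Only and 554 ± 129 CPM in FKl/l (SD, n = 6 each; log2 fold change 0.70, SE 0.0878, adjusted p = 0.000168), with 547 CPM in FKl/l MHC+. The zinc finger gene Zcchc3 was at 7.36 ± 1.55 against 4.19 ± 0.661 CPM (log2 fold change 0.80, SE 0.121, adjusted p = 0.00188). The riboflavin transporter Slc52a3 was at 1.42 ± 0.283 against 0.302 ± 0.121 CPM (log2 fold change 2.24, SE 0.334, adjusted p = 0.00188). The small GTPase Rem1 was lower, at 4.14 ± 0.324 against 6.35 ± 0.691 CPM (log2 fold change -0.61, SE 0.098, adjusted p = 0.00377). The chromatin regulator Asxl1 was higher (log2 fold change 0.45, SE 0.0831, adjusted p = 0.0242) and 6820408C15Rik lower (log2 fold change -0.79, SE 0.137, adjusted p = 0.0116). Slc52a3 and 6820408C15Rik were named after their values were seen. The 7th gene, Nt5dc2 on chromosome 14 (31131053 to 31139124), had a log2 fold change of 0.39 (SE 0.0772, adjusted p = 0.0488). Its call was lost in 15 of the 24 fits that left out 1 library (adjusted p up to 0.126), and that of 6820408C15Rik without MHC CRE Only 1-2 (0.0513). That of Asxl1 was lost without FKl/l 1-1, 1-2 or 1-3, MHC CRE Only 1-2 or the library labelled MHC CRE Only 1-3 (up to 0.125).

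Within 5 Mb of Fkbp1a, 5.61% of the 107 genes tested were called between MHC CRE Only and FKl/l, against 0.00631% of genes elsewhere (Fisher's exact test, two-sided, p = 5.47e-13). Of the 6, Pygb, Zcchc3, Slc52a3 and Rem1 were also called between FKl/l MHC+ and MHC CRE Only, with the sign that sets MHC CRE Only apart from both floxed genotypes, at log2 fold changes of -0.70, -0.86, -2.35 and 0.41. That of Rem1 (adjusted p = 0.0266) was lost without MHC CRE Only 1-1, the library labelled MHC CRE Only 1-3 or FKl/l MHC+ 1-2 or 1-3 (up to 0.0775). Against FKl/l none of these 4 was called in FKl/l MHC+ or FKl/l MCK+. Asxl1 was higher in FKl/l MHC+ (log2 fold change 0.36, adjusted p = 0.0198, and up to 0.0721 without FKl/l 1-2 or 1-3 or FKl/l MHC+ 1-1).

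**Figure D3:**
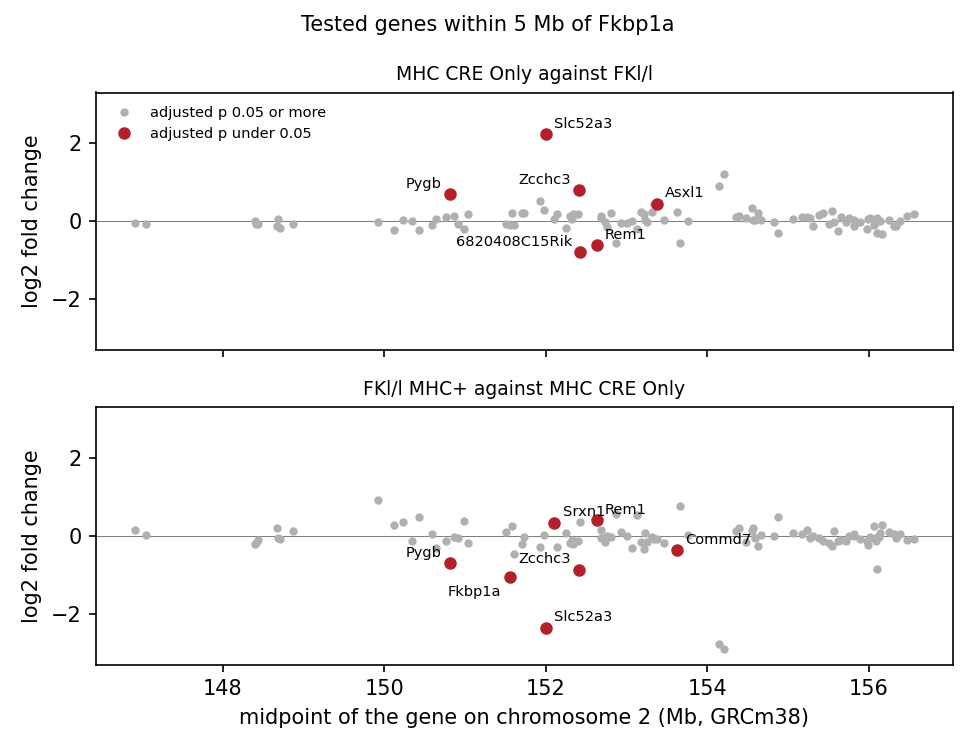
Each point is a gene tested within 5 Mb of Fkbp1a, with its midpoint on chromosome 2 (Mb, GRCm38) on the horizontal axis and its log2 fold change on the vertical axis. Panels show MHC CRE Only against FKl/l (top) and FKl/l MHC+ against MHC CRE Only (bottom). Named red points have an adjusted p under 0.05, with Slc52a3 at 2.24 in the upper and -2.35 in the lower panel, and MHC CRE Only includes the library labelled MHC CRE Only 1-3.

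Of the 40 gene lists, 9 were called between MHC CRE Only and FKl/l at the preset correlation, 3 by fry and 0 with an estimated correlation, and 5 without the library labelled MHC CRE Only 1-3. Unfolded protein response genes were higher (21 genes, adjusted p = 2.09e-06, or adjusted p = 0.21 with an estimated correlation), with 0 called over all genes and 11 adjusted over the list alone. Skeletal muscle markers were higher (10 genes, adjusted p = 0.00454, or adjusted p = 0.21 with an estimated correlation), with 0 called and 3 adjusted over the list alone. Sex-linked transcripts were lower (6 genes, adjusted p = 0.00549, or adjusted p = 0.21 with an estimated correlation), with 0 called and 2 adjusted over the list alone. Branched-chain amino acid breakdown was lower (adjusted p = 0.00595, or adjusted p = 0.779 with an estimated correlation). Interferon response genes were lower (adjusted p = 0.00595, or adjusted p = 0.918 with an estimated correlation), a call lost without the library labelled MHC CRE Only 1-3 or FKl/l 2-2 (up to 0.867). Lymphocyte markers were lower (adjusted p = 0.00654, or adjusted p = 0.779 with an estimated correlation), a call lost without MHC CRE Only 1-1, the library labelled MHC CRE Only 1-3 or FKl/l 2-2 (up to 0.124). Immediate early genes were lower (adjusted p = 0.00787, or adjusted p = 0.918 with an estimated correlation, and 0.109 without FKl/l 1-1). Atrial cardiomyocyte markers were lower (adjusted p = 0.00787, or adjusted p = 0.779 with an estimated correlation). Ion channel and gap junction genes were higher (adjusted p = 0.0183, or adjusted p = 0.779 with an estimated correlation), and both lists had the opposite sign in batch 2 (adjusted p = 0.389 and 0.667). These calls were lost without the library labelled MHC CRE Only 1-3, and without FKl/l 1-3 for the former (up to 0.412) or FKl/l 1-1 for the latter (up to 0.172).

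The 7 genes called between MHC CRE Only and FKl/l compare with 17 in batch 1 alone (2 of them among the 7) and 82 in batch 2 alone (3), and 2069 genes had an unadjusted p under 0.05. The effects on Asxl1 and Pygb also differed in size between batches by an interaction test, with log2 fold changes of 0.74 and 0.96 in batch 1 and 0.18 and 0.45 in batch 2. The count of 7 was 4 without MHC CRE Only 1-2, 13 without FKl/l MHC+ 2-2, 18 without MHC CRE Only 1-1 and 1 without genes within 5 Mb of Fkbp1a. It was 0 with a term for Y-linked transcripts (edgeR), 312 with a term for airway transcripts, 169 by DESeq2, 39 by limma voom and 15 with no filter on low counts. It was 4 without a batch term, 4 without the library labelled MHC CRE Only 1-3, MHC CRE Only 2-3 and FKl/l 1-1, 3 in a fit of the 2 genotypes and 2 tested against a fold of 1.2.

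The comparison of the deletions with each other, FKl/l MHC+ against FKl/l MCK+, sets the earlier against the later driver at Fkbp1a levels that did not differ by the test. It gave 345 genes, 158 higher and 187 lower in FKl/l MHC+, 40 of them at least 2-fold. Endothelial transcripts were lower in FKl/l MHC+, with the junction protein Cdh5 (VE-cadherin) at 110 ± 9.37 against 142 ± 19.8 CPM (SD, n = 6 each; log2 fold change -0.36, SE 0.0704, adjusted p = 0.0058). Some fast skeletal muscle transcripts were higher, with Mylpf at 1.85 ± 0.767 against 0.465 ± 0.15 CPM (log2 fold change 1.97, SE 0.272, adjusted p = 0.000132). So was the fetal and stress program, with Ankrd1 at 2433 ± 888 against 1207 ± 506 CPM (log2 fold change 1.04, SE 0.144, adjusted p = 0.000238). Dystrophin transcripts were at 20.3 ± 2.63 against 34.8 ± 2.23 CPM (Dmd, log2 fold change -0.78, SE 0.0755, adjusted p = 7.45e-07).

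Of 18 endothelial markers, 9 were called lower and 0 higher in FKl/l MHC+ than in FKl/l MCK+, with 13 lower adjusted over the list alone (adjusted p = 1.34e-15, or adjusted p = 0.0179 with an estimated correlation). Called members included Robo4 (log2 fold change -0.43, SE 0.067, adjusted p = 0.000622) and the receptors Ptprb (log2 fold change -0.31, SE 0.0635, adjusted p = 0.0084) and Tek (log2 fold change -0.31, SE 0.0632, adjusted p = 0.00944). Of 16 Notch pathway genes, 2 were called lower and 14 not, with 6 lower and 1 higher adjusted over the list alone (adjusted p = 0.000837, or adjusted p = 0.0426 with an estimated correlation). These were the endothelial receptor Notch4 (log2 fold change -0.47, SE 0.083, adjusted p = 0.00226) and the ligand Dll4 (log2 fold change -0.43, SE 0.0929, adjusted p = 0.0111). The estimated-correlation call of the Notch pathway was lost in 12 of the 24 fits that left out 1 library, with the highest adjusted p of 0.0775 without FKl/l MHC+ 2-1. Of 10 skeletal muscle markers 3 were called higher and 4 adjusted over the list alone (adjusted p = 1.56e-06, or adjusted p = 0.022 with an estimated correlation). Among them were Mybpc2 (log2 fold change 0.99, SE 0.191, adjusted p = 0.00944) and Atp2a1 (log2 fold change 1.00, SE 0.206, adjusted p = 0.0111). Of the 24 fetal and stress genes 4 were called higher, with 7 higher and 1 lower adjusted over the list alone (adjusted p = 5.78e-07, or adjusted p = 0.022 with an estimated correlation). Mt2 rose 3.91-fold (log2 fold change 1.97, SE 0.312, adjusted p = 0.00224) and Uchl1 had a log2 fold change of 0.54 (SE 0.0913, adjusted p = 0.00152).

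Fibroblast markers were lower in FKl/l MHC+ than in FKl/l MCK+, with 4 of 18 called lower and 7 adjusted over the list alone (adjusted p = 6.82e-06, or adjusted p = 0.104 with an estimated correlation). The serine protease Htra3 was among them (log2 fold change -0.35, SE 0.0657, adjusted p = 0.00434), as was Fbln1 (log2 fold change -0.41, SE 0.0938, adjusted p = 0.0173, and 0.0569 without FKl/l MHC+ 2-3). The heat shock response was higher (2 of 18 called, 7 adjusted over the list alone, adjusted p = 1.56e-06, or adjusted p = 0.267 with an estimated correlation). Immediate early genes were higher (1 of 23 called, 3 adjusted over the list alone, adjusted p = 1.91e-06, or adjusted p = 0.334 with an estimated correlation). Targets of p53 were higher (4 of 25 called higher, 5 higher and 1 lower adjusted over the list alone, adjusted p = 0.00168, or adjusted p = 0.169 with an estimated correlation). Cdkn1a was at a log2 fold change of 1.06 (SE 0.179, adjusted p = 0.0031). Antioxidant targets of NRF2 were higher (3 of 32 called, 5 adjusted over the list alone, adjusted p = 0.0036, or adjusted p = 0.217 with an estimated correlation). The epoxide hydrolase Ephx1 was at 0.49 (SE 0.0702, adjusted p = 0.000238). Glycolysis genes (25, adjusted p = 0.00371, or adjusted p = 0.334 with an estimated correlation) and integrated stress response genes (25, adjusted p = 0.00652, or adjusted p = 0.128 with an estimated correlation) were higher. The former had the opposite sign in batch 2 (adjusted p = 0.826). Branched-chain amino acid breakdown was lower (21 genes, adjusted p = 0.0104, or adjusted p = 0.476 with an estimated correlation). Smooth muscle and pericyte markers were lower with Pdgfrb called (adjusted p = 0.0125, or adjusted p = 0.217 with an estimated correlation). Sarcomere genes were higher (adjusted p = 0.044, or adjusted p = 0.688 with an estimated correlation). These last 3 list calls were lost, in this order, without FKl/l MCK+ 2-1 or 1-3 (up to 0.0698), without FKl/l MHC+ 2-1 (0.0701), and without FKl/l MCK+ 1-1 or 1-2 or FKl/l MHC+ 1-2, 1-3, 2-2 or 2-3 (up to 0.164).

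Other genes higher in FKl/l MHC+ than in FKl/l MCK+ were the secreted protein Ndnf (log2 fold change 1.19, SE 0.14, adjusted p = 2.78e-05) and Epn3 (log2 fold change 1.08, SE 0.21, adjusted p = 0.0102). Kcne1 and Masp1, higher in both deletions, had log2 fold changes between them of 0.01 (adjusted p = 0.994) and 0.55 (adjusted p = 0.00466). Lower genes were Dcakd (log2 fold change -0.72, SE 0.0809, adjusted p = 6.93e-06), and the phosphatase subunit Ppp2r3a at 167 ± 8.46 against 254 ± 26.2 CPM (log2 fold change -0.60, SE 0.0772, adjusted p = 4.6e-05). The junction protein Ctnna3 was also lower (log2 fold change -0.56, SE 0.091, adjusted p = 0.00104). All 345 genes had the same sign in both batches, with 210 called in batch 1 alone (90 of them among the 345) and 172 in batch 2 alone (85). Higher genes made up 45.8% of the calls, and 56.5% with no filter on low counts and 57.2% in libraries without mitochondrially encoded genes. The count of 345 was 144 to 175 without FKl/l MHC+ 1-2, 1-3 or 2-3 or FKl/l MCK+ 1-1, and 219 and 225 without FKl/l MCK+ 1-3 and 1-2. It was 103 without a batch term, 17 tested against a fold of 1.2, 562 by DESeq2 and 822 by limma voom.

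The list calls that held with an estimated correlation were those of skeletal muscle markers and the fetal and stress program in FKl/l MHC+ against FKl/l. The same held for the unfolded protein response, the fetal and stress program and sex-linked transcripts against MHC CRE Only, for the FKBP family there only with Fkbp1a in the list, and for endothelial markers, the Notch pathway, skeletal muscle markers and the fetal and stress program against FKl/l MCK+. Lists called in no comparison by camera or by fry's directional test were calcium handling, oxidative phosphorylation, oxidant sources, TGF-beta and BMP targets, the circadian clock, and markers of ventricular cardiomyocytes, the conduction system, epicardium, Schwann cells, granulocytes and mast cells, and lung. Fry's mixed test, which looks for members changed in either direction, called 4 of these in at least 1 comparison. They were TGF-beta and BMP targets (lowest adjusted p = 2.9e-07), the conduction system (4.74e-06), oxidant sources (0.000773) and the circadian clock (0.0248).

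The authors' deposited tables, which test against a minimum fold, called 2, 23, 11, 1 and 14 of 16363 genes in the order of the comparisons above. Each of those genes was also called here with the same sign. Across genes, the log2 fold changes of the deposited tables and of the fit here had Spearman correlations between 0.956 and 0.969.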

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

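Both tests that weigh explanations in this part were chosen after the result was seen, while the counts of batch-dependent genes over other splits of the libraries were planned before them.

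The library labelled MHC CRE Only 1-3 stood apart from the other libraries of its genotype in Fkbp1a, at 81.8 CPM where the other 5 had 122 to 138 (gap to the nearest library over the group's range, 0.711). A deletion library under a wrong label was weighed by genes near Fkbp1a that set MHC CRE Only apart from the floxed genotypes without this library. On a scale with 0 at the floxed genotypes and 1 at the other MHC CRE Only libraries, its positions for Pygb, Slc52a3, Zcchc3, Rem1 and Commd7 (chosen after their values were seen) had a median of 0.724 (0.335 to 1.32, median absolute deviation 0.448). MHC CRE Only 1-1 and 1-2 had medians of 1.05 (0.615 to 1.15) and 0.883 (0.742 to 1.19), so each also has a gene under 0.75. No position was computed for a single floxed library, so the spread around 0 is not known. For this reason and the mixed batches, these 5 genes argue only weakly against a wrong label. A candidate explanation that stays open is 1 floxed copy beside the MHC-Cre, or RNA mixed in from a deletion library, which would put these genes between the groups. With 3 of the 5 genes at a position under 0.75 and the others at 0.941 and 1.32, it cannot be told apart from an MHC CRE Only heart with a low Fkbp1a level, and no biological explanation was tested.

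The same gap measure put this library apart in other genes too. It was highest in Masp1 at 17.5 CPM against 10.5 to 12.8 in the other 5 (0.668), in Mt2 at 15.8 against 8.73 to 11 (0.683) and in Dbp at 97.8 against 14.6 to 23.7 (0.89). It was also highest in Notch4 at 40.3 against 29 to 30.9 (0.834). It was lowest in Dmd at 22.7 against 28.7 to 30.9 (0.736). For Masp1, Mt2 and Dmd this is the direction of FKl/l MHC+ against FKl/l (log2 fold changes 1.24, 1.68 and -0.82), and Notch4 was not called there (-0.13, adjusted p = 0.494). Genes picked because this library stands apart in them do not decide its genotype. Chance alone is expected to set apart about 1 group in 20. Over 71 genes named in the text and 3 library measures, 296 groups were examined and 21 had such a library, where chance gives about 14.8. Of the 21, 6 were this library. In Scgb1a1 and Dbp, named after their values were seen, lie 4 of the 21, so the count does not show an excess over chance.

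Other libraries stood apart from the other 5 of their genotype in 1 to 3 genes each. The airway transcript Scgb1a1 was at 108 CPM in FKl/l 1-1 against 0.0261 to 1.9 (0.983), at 365 in MHC CRE Only 2-3 against 0.124 to 18.9 (0.948) and at 9.34 in FKl/l MCK+ 1-2 against 0.101 to 1.63 (0.835). FKl/l 1-1 was also highest in Thbs4, at 10.3 against 4.55 to 6.53 (0.656), and in Edn3, at 3.09 against 0.808 to 1.56 (0.669), and FKl/l 1-2 lowest in Mt2, at 4.94 against 7.92 to 9.55 (0.646). Among MHC CRE Only, 1-1 was highest in Cdh5, at 143 against 115 to 125 (0.627), 1-2 highest in Ccl7, at 1.54 against 0.467 to 0.865 (0.629), and 2-2 lowest in Fkbp10, at 29.6 against 33.6 to 35.4 (0.693). Among FKl/l MCK+, 2-2 was highest in Mylpf, at 0.749 against 0.303 to 0.464 (0.64), and 2-3 highest in Epn3, at 50.1 against 21.3 to 29.7 (0.707). Among FKl/l MHC+, 2-1 was highest in Kcne1, at 12.9 against 5.61 to 7.82 (0.696), and lowest in Hsp90aa1, at 104 against 237 to 311 (0.641). FKl/l MHC+ 2-3 was highest in Gdf15, at 13.9 against 1.5 to 5.64 (0.665), and in Fzd2, at 25.6 against 18.2 to 20.5 (0.688). All of these genes are named in the text and were examined because of that.

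The effect of genotype differed between batches, by an interaction term in edgeR's quasi-likelihood fit, for 892 genes in MHC CRE Only against FKl/l and for 491 in FKl/l MHC+ against MHC CRE Only. For these counts 1 of the 100 splits of the libraries within batches gave as many in each, the real one, with a highest other value of 182 and 282, so counts as large were rare among these splits. Both rest on single libraries. Without MHC CRE Only 2-3, the library labelled MHC CRE Only 1-3 or FKl/l 2-3 the count of 892 was 0. It was 2, 205, 427, 581 and 594 without FKl/l 1-3, FKl/l 2-1, MHC CRE Only 2-1, FKl/l 2-2 and MHC CRE Only 2-2, and 1297 without MHC CRE Only 1-1. The count of 491 was 40, 78, 104 and 320 without FKl/l MHC+ 2-2, 1-2, 1-3 and 1-1. It was 59, 78, 132 and 226 without the library labelled MHC CRE Only 1-3, MHC CRE Only 2-3, 2-1 and 2-2, and 940 and 941 without MHC CRE Only 1-1 and FKl/l MHC+ 2-1.

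In FKl/l MHC+ against FKl/l the effect on 1 gene differed between batches, Ypel2 (adjusted p = 0.0452), with 11 of the 100 splits giving as many and up to 269. In FKl/l MHC+ against FKl/l MCK+ it differed for 3 genes, Vegfa (adjusted p = 0.0254), Lrtm1 and Tmppe, with 9 of the 100 splits giving as many and up to 627. Chance cannot be excluded for either count. Splits with several times the real count may reflect a structure of the samples, which was not tested. These 4 genes were named after their values were seen. Without 1 library the counts lay between 0 and 109, highest without FKl/l 1-1, and between 0 and 363, highest without FKl/l MCK+ 1-3. In FKl/l MCK+ against FKl/l edgeR called 0 genes, 444 at an unadjusted p under 0.05, and all 100 splits gave as many, with at most 5, and the count was 1 without FKl/l 1-2.

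Count table entries that name a transcript and no gene, used in no comparison, held 4.28% of the counts of FKl/l MCK+ 2-1, and 3.68% in FKl/l MCK+ 2-3, above the 1.22 to 3.24% in the 12 control libraries. Most of this share was in 1 entry annotated as ribosomal RNA, which held 4.2 and 3.6% of the counts of these 2 libraries.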

How the results depend on the processing

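The test against a fold of 1.2, the addition of transcript-named entries to their genes, the term for airway transcripts, the fits without 3 libraries or without genes near Fkbp1a, the FKBP list without Fkbp1a, and all refits of the batch interaction were chosen as tests after the results were seen, and the other alternatives were fixed before the data were examined. Counts below are in the order FKl/l MCK+ against FKl/l, FKl/l MHC+ against FKl/l, FKl/l MHC+ against MHC CRE Only, MHC CRE Only against FKl/l and FKl/l MHC+ against FKl/l MCK+, then FKl/l MHC+ against both controls where given, and the cause of a change was not tested unless it is stated.

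The main counts of genes called were 8, 274, 299, 7, 345 and 95. DESeq2 gave 17, 558, 571, 169, 562 and 185, and limma voom with quality weights 13, 881, 708, 39, 822 and 292. Without a batch term they were 5, 120, 42, 4, 103 and 29, where the differences between batches enter the spread. Batch 1 alone gave 1, 209, 79, 17, 210 and 26 and batch 2 alone 8, 161, 924, 82, 172 and 97, from 3 libraries per genotype. A fold minimum of 2 left 2, 38, 36, 1, 40 and 18, and a test against a fold of 1.2 left 3, 42, 17, 2, 17 and 13, both stricter by construction. With a term for Y-linked transcripts the counts were 4, 301, 51, 0, 325 and 31, and with one for airway transcripts 11, 326, 516, 312 and 404 for the 5 comparisons. The Y-linked term can take up genotype differences, since it includes Ddx3y, which was called in FKl/l MHC+ against MHC CRE Only. Without the library labelled MHC CRE Only 1-3, MHC CRE Only 2-3 and FKl/l 1-1 they were 11, 506, 230, 4, 492 and 133. Without a filter on low counts MHC CRE Only against FKl/l gave 15, in a fit of the 2 genotypes 3, and without genes within 5 Mb of Fkbp1a 1, since 6 of the 7 lie there. RLE size factors, the stricter filter, the removal of mitochondrially encoded genes and the addition of transcript-named entries kept these 6 counts within 1.5 times. With 1 library left out they lay between 5 and 11, 155 and 420, 135 and 496, 4 and 18, 144 and 497, and 52 and 165. In 5 libraries per genotype a change of call may come from the smaller number alone.

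The replicate number does not pair the libraries, whose deviations correlated between -0.238 and 0.162 over 30 pairs with the same number, 2 of them over 0.1. With the number as a block the counts were 7, 226, 215, 6, 231 and 76.

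In the 3 comparisons that called it, Fkbp1a kept its sign in every fit and its call in all but those of batch 1 alone, where the log2 fold changes of -0.98 in FKl/l MCK+ against FKl/l and -0.80 in FKl/l MHC+ against MHC CRE Only had adjusted p = 1 and 0.122. Over 211 calls of genes that the text names or the naming rule takes, none changed sign. Of these, 134 were lost in batch 1 alone, 108 in batch 2 alone, 154 against a fold of 1.2, 86 without a batch term and 63 with a Y-linked term. Another 47 were lost in fits of the 2 genotypes, 27 with the replicate number as a block, 25 without a filter and 23 without the 3 libraries. At most 6 were lost by RLE, DESeq2 or limma voom, without mitochondrially encoded genes or with an airway term, and none with transcript-named entries added. The stricter filter kept all of the 208 calls it tested.

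Lists called at the preset correlation were 9, 15, 18, 9 and 14. With an estimated correlation 0, 2, 4, 0 and 4 were called and by fry 0, 7, 8, 3 and 9, or 4, 19, 19, 5 and 19 by its mixed test for members changed in either direction. Without Fkbp1a the FKBP list was not called in FKl/l MHC+ against MHC CRE Only (adjusted p = 0.122, or adjusted p = 0.328 with an estimated correlation). Batch 1 alone called 14 in FKl/l MCK+ against FKl/l and 15 in MHC CRE Only against FKl/l, and batch 2 alone 17 in the latter. With 1 library left out the counts lay between 8 and 19, 11 and 19, 14 and 18, 5 and 12, and 13 and 15. A list took the opposite sign in batch 2 alone for erythroid markers in FKl/l MCK+ against FKl/l (adjusted p = 0.774), the tricarboxylic acid cycle in FKl/l MHC+ against MHC CRE Only (0.196), ion channels and atrial markers in MHC CRE Only against FKl/l (0.667 and 0.389) and glycolysis in FKl/l MHC+ against FKl/l MCK+ (0.826). The same held in batch 1 alone for fibroblast markers in FKl/l MHC+ against MHC CRE Only (0.933), and in MHC CRE Only against FKl/l for branched-chain amino acid breakdown with a Y-linked term (0.651) and for interferon response genes without FKl/l 2-2 (0.867), a list with adjusted p = 8.17e-05 without FKl/l 2-1.

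Genes whose effect differed between batches numbered 0, 1, 491, 892 and 3, and 0, 143, 0, 0 and 114 without the 3 libraries named above. With 1 library left out they lay between 0 and 1, 0 and 109, 40 and 941, 0 and 1297, and 0 and 363. The 7 genes shared by the deletions were 1 (median) with the FKl/l libraries split, from 3 controls each, where fewer calls can lower the overlap by themselves. At 6 libraries per genotype most changes of 1.3-fold are missed, as the simulated data showed, so a gene that was not called may still differ.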

Other observations

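In this part the genes of the first paragraph, both patterns weighed and the split counts of genes and lists called against FKl/l or MHC CRE Only were chosen as tests only after the result was seen, while the other split counts were planned before.

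Of the 95 genes that set FKl/l MHC+ apart from both controls, 58 were also called against FKl/l MCK+ with the same sign, 40 higher and 18 lower. These comparisons share the FKl/l MHC+ libraries, so part of the agreement is expected, and no value for unchanged libraries was computed. Beside those described above they held Ucp2, a mitochondrial uncoupling protein, at 235 ± 28.1 CPM in FKl/l MHC+ against 122 ± 26.5 in FKl/l, 160 ± 33 in MHC CRE Only and 156 ± 24 in FKl/l MCK+ (SD, n = 6 each; adjusted p = 1.28e-07, 0.000969 and 0.000472). The receptor kinase Grk5, which desensitizes G protein-coupled receptors, was at 65.2 ± 8.48 CPM against 37.9 to 42.7 (log2 fold changes 0.73, 0.61 and 0.78). The Wnt receptor Fzd2 was at 20.7 ± 2.54 against 10.5 to 13.9 CPM (log2 fold changes 1.00, 0.82 and 0.59). The monocyte-attracting chemokines Ccl2 and Ccl7 were at 2.99 ± 1.89 and 2.89 ± 1.77 CPM against at most 1.18 and 0.837. The peptide hormone endothelin 3 (Edn3) was at 4.75 ± 1.59 against at most 1.89 CPM. Among the lower genes was Ltbp4, a matrix protein that binds latent TGF-beta, at 214 ± 28.4 against 291 to 303 CPM (log2 fold changes -0.44, -0.48 and -0.51). Of these calls, that of Edn3 against FKl/l MCK+ (adjusted p = 0.0199) was lost without FKl/l MHC+ 2-3 (0.0599).

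The genes called between MHC CRE Only and FKl/l lay near Fkbp1a, 6 of 7 within 5 Mb. Chance position on the genome is argued against, since 10000 random draws of as many tested genes put at most 2 in that window (permutation p = 1e-04, the smallest they can give). The MHC-Cre transgene alone, which FKl/l MHC+ also carries, is argued against for 4 of the 6, Slc52a3, Zcchc3, Pygb and Rem1, which were called between FKl/l MHC+ and MHC CRE Only with the opposite sign (Rem1 not without MHC CRE Only 1-1, the library labelled MHC CRE Only 1-3 or FKl/l MHC+ 1-2 or 1-3, adjusted p up to 0.0775). For Asxl1 and 6820408C15Rik the transgene cannot be told apart from other explanations, since neither passed that test (lowest adjusted p = 0.181), and over all 6 genes the log2 fold changes in FKl/l MHC+ against FKl/l, signed as in MHC CRE Only, had a median of 0.10 (-0.11 to 0.42) where MHC CRE Only had 0.74 (0.45 to 2.24). A candidate explanation is a chromosome segment carried with the floxed allele in the 3 floxed genotypes, which the same 4 calls fit, and this is a hypothesis found and tested on the same libraries.

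Of the 10 skeletal muscle markers, the fast-muscle transcripts Mylpf, Atp2a1, Mybpc2 and Tnni2 were called higher in FKl/l MHC+ against FKl/l and 6 were not called, 1 of these lower adjusted over the list alone. Skeletal muscle tissue in the samples is argued against, since the fast myosin heavy chains Myh1, Myh2 and Myh4, abundant in such tissue, summed to 0.0797 ± 0.0512 CPM in FKl/l MHC+ and 0.111 ± 0.096 in FKl/l (SD, n = 6 each), while Mybpc2 was at 50.1 and 23.4 CPM. The MHC-Cre transgene as the whole cause is argued against for 2 of the 4, Mylpf and Mybpc2, which were also higher than in MHC CRE Only, calls that end without FKl/l MHC+ 1-2 or 2-3 (adjusted p up to 0.0873) and for Mybpc2 also without FKl/l MHC+ 1-3 or MHC CRE Only 1-2, 2-1, 2-2 or 2-3 (up to 0.0723). The transgene stays open for Atp2a1 and Tnni2 (lowest adjusted p = 0.138) and as a part of the rise, since Mylpf was at 0.838 CPM in MHC CRE Only and 0.37 in FKl/l (log2 fold change 1.18, adjusted p = 0.087) and the list was higher there (adjusted p = 0.00454, or adjusted p = 0.21 with an estimated correlation). The level of Fkbp1a alone stays open as a cause, although 3 of the 4, Mylpf, Atp2a1 and Mybpc2, were also higher than in FKl/l MCK+. The whole-heart level did not differ between the deletions by the test (log2 fold change -0.14, SE 0.124), which does not show equal levels. Its level in cardiomyocytes was not measured. The earlier start of deletion, which the design names, may contribute but was not tested apart from other differences between the drivers.

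Other splits of the 12 libraries of each pair of genotypes were refitted, 100 with the real one. For genes called, 2 of the 100 splits gave as many in FKl/l MCK+ against FKl/l (8, highest other 13), and 1, the real one, in each other comparison. The real counts were 274 in FKl/l MHC+ against FKl/l (highest other 192), 299 against MHC CRE Only (113), 7 in MHC CRE Only against FKl/l (2) and 345 in FKl/l MHC+ against FKl/l MCK+ (18). Counts as large were rare among such splits in all 5, though a split with 13 genes exceeded the real 8. These splits were not balanced by batch, and 100 of them cannot show a share below 1 of 100. The splits with 192, 113, 2 and 18 genes each exchanged 1 library between the groups. Against both controls, 1 of 100 splits of the 18 libraries gave as many genes (95, highest other 0). Such splits give almost no calls, so that 0 is no test. For the overlap of the deletions, 1 of 100 splits, the real one, gave as many (7, highest other 0), but this does not test sharing beyond the common controls. With the controls split between the deletions, 18 splits shared a median of 1 gene (1 to 3).

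For gene lists called at the preset correlation chance cannot be excluded in FKl/l MCK+ against FKl/l, where 55 of the 100 splits gave as many (9, highest other 18), or in FKl/l MHC+ against FKl/l with 14 (15, highest other 18). The same holds in MHC CRE Only against FKl/l with 72 (9, highest other 19) and in FKl/l MHC+ against FKl/l MCK+ with 18 (14, highest other 19). A count as large was rare in FKl/l MHC+ against MHC CRE Only, with 3 (18, highest other 19). With an estimated correlation a count as large was rare in FKl/l MHC+ against FKl/l, with 3 of the 100 splits (2 lists, highest other 4). It was also rare in FKl/l MHC+ against MHC CRE Only with 1 (4 lists, highest other 1) and against FKl/l MCK+ with 1 (4 lists, highest other 2). All 100 splits gave as many as the 0 lists of FKl/l MCK+ and of MHC CRE Only against FKl/l (highest other 1 and 2).

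The clock-controlled transcription factor Dbp, chosen after its values were seen, was at 97.8 CPM in the library labelled MHC CRE Only 1-3 and between 12.2 and 35.6 CPM in the other 23 libraries.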
